A study of Daphnia magna with 16 samples.

How the data were processed

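Ovary RNA of Daphnia magna was measured in 16 samples, each a pool of 3 animals per the labels, in 4 groups of 4: fenoxycarb, the DMF control of the fenoxycarb experiment, methyl farnesoate, and the DMF control of the methyl farnesoate experiment. Groups and replicate numbers were taken from the source names in the labels. Each sample is taken as a separate pool.

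Per the labels' protocols, total RNA was extracted with TRIZOL, purified, checked on a Bioanalyzer, labelled with Cy3 as complementary RNA in the presence of Agilent spike-in RNA, and hybridised to 1-colour arrays. The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1, which subtracted the background and removed spatial trends within each array to give the processed signal, with no scaling between arrays. The deposited series table holds the same intensity values: the ratio of its values to the processed signal was 1.00 for each of 43803 probes on every array, with column medians from 35.4 to 113, so it offers no alternative, and calls from it were identical. The flags for spots well above background, saturated or outlying are other values of the same scanner software, per the file headers.

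The array held 45220 spots, of which 1417 were controls and 43803 carried 1 probe each. Probes were 50 bases (26510) or 60 bases (17293) long, with 38705 distinct sequences. Every probe's description in the files is a placeholder and its gene name equals its ID, and 0 IDs matched the 28335 genes of the reference table, so no probe could be named. The gene lists and markers of other tissues fixed before the data were examined, the gene set tests on them, counts of genes instead of probes and the choice of a probe for a gene could therefore not be formed and are not reported here. Probes were instead gathered into 22054 sequence groups, joined by a shared ID stem or an identical stretch of 25 bases on the same strand. The largest group held 9 probes. This grouping was chosen after the data were seen.

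Values were log2 of the processed signal minus each array's 75th percentile of it. Control spots were left out and spots flagged as outliers were set to missing, between 0 and 12 per array. Probes were kept if well above background on all 4 arrays of at least 1 group, which left 32314. One model of 4 group means was fitted to all 16 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (12 residual and 2.18 prior degrees of freedom). Contrasts were each treatment minus its own DMF control, the mean of both effects, their difference, and the DMF control of the fenoxycarb experiment minus that of the methyl farnesoate experiment. All p-values were two-sided and adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. Standard errors are those of the moderated test.

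Where a probe was not well above background on any array of a group, the brighter group is given as at least N-fold higher. That bound sets the bright group's mean against the mean over the dim group's arrays of the higher of the probe's own signal and the lowest signal among probes well above background on that array, all as normalized log2 values. Named probes followed a rule fixed before the data were examined: 2 IDs that rose and 2 that fell for each comparison. They were taken by size for each treatment and for the control groups, by smallest adjusted p for the mean of both, and by smallest unadjusted p for the difference, where none passed. Any other ID was named after its values were seen.

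The slide and scan session came from the files. Each of 4 slides held 2 treated arrays and 2 of their own controls, and each of 2 scan sessions held 1 experiment. Alternatives were normexp background correction (offset 50) on the mean and local background signals, quantile normalization, median centring, no filter, a filter on all 16 arrays, slide or replicate number as a block, own 8 arrays only, each array left out, eBayes with trend and robust settings, and a threshold of at least 2-fold. Alternatives added after the data were seen left out fenoxycarb replicate 3 and DMF replicate 4 of the fenoxycarb experiment, weighted arrays by their spread, replaced high local backgrounds before normexp, or counted 1 probe per sequence group.

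The same functions were tested on simulated data: 5 runs per comparison, each with 32314 probes, their fitted spread and 200 changed probes. Noise was normal, independent between probes, and of the same spread on all arrays for a given probe. The simulated data thus lacked groups of unequal spread, arrays far from their group and links between probes, which the real data have. The shares that follow hold for that setting and not for the real arrays. For fenoxycarb against DMF 17.2% of changes of 1 log2 unit, 64.0% of 2, 84.8% of 3 and 95.2% of 4 were called, and 5.36% of calls were false. For methyl farnesoate against DMF the shares were 14.4%, 64.4%, 81.6% and 97.2%, with 4.02% false. For the difference between the treatments they were 1.6%, 39.6%, 64.0% and 79.6%, with 7.41% false.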

Results

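Ovaries of the water flea Daphnia magna were compared after exposure to either of a pair of juvenile hormone agonists. Fenoxycarb is a synthetic juvenile hormone analog with a carbamate group, and methyl farnesoate is the sesquiterpenoid that serves crustaceans as their juvenile hormone. In daphniids such compounds, given while oocytes mature, lead to male offspring. The labels describe the treated ovaries as holding male oocytes and the ovaries given only the solvent N,N-dimethylformamide (DMF) as holding female oocytes. Each treatment had its own DMF control, which gave 4 groups of 4 samples, and each sample pooled the ovaries of 3 animals. Total RNA was labelled with Cy3 and hybridised to 1 array per sample, 16 arrays in all, on a custom design, of which 32314 non-control probes passed the filter on dim probes. The 75th percentile of the processed signal ran from 195.3 to 359 in the 8 arrays of the fenoxycarb experiment and from 590 to 809 in the 8 arrays of the methyl farnesoate experiment. The share of probes well above background was 62.3 to 68.1% in the first and 73.9 to 83.4% in the second. The files pair no probe with a gene name, and 0 probe IDs matched the reference gene table, so probes are reported by ID.

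The arrays did not separate by treatment. A pair of arrays stood furthest from the rest, and the other 14 split by experiment. Within the methyl farnesoate experiment every pair of arrays correlated at 0.940 or more across probes. In the fenoxycarb experiment 6 of the 8 arrays correlated at 0.985 or more with each other. The other arrays, fenoxycarb replicate 3 and DMF replicate 4, had median correlations of 0.801 and 0.910 with their own groups but 0.953 with each other. In fenoxycarb replicate 3, 8222 probes lay over 2 log2 units above the mean of those 6 arrays and 4058 lay as far below. Its 75th percentile of processed signal was 195.3, against 326 or more in those 6, but its median was higher, 43.2 against 35.4 to 39.3. Scaling to the 75th percentile thus raised its probes relative to those 6, which favours the count above. Fenoxycarb replicate 3 and DMF replicate 4 sit in opposite groups and add to the spread of every test that includes them. The median SD between replicates was 0.79 in the fenoxycarb group, 0.55 in its DMF control, 0.22 in the methyl farnesoate group and 0.15 in its DMF control, all in log2 units and n = 4.

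**Figure D1:**
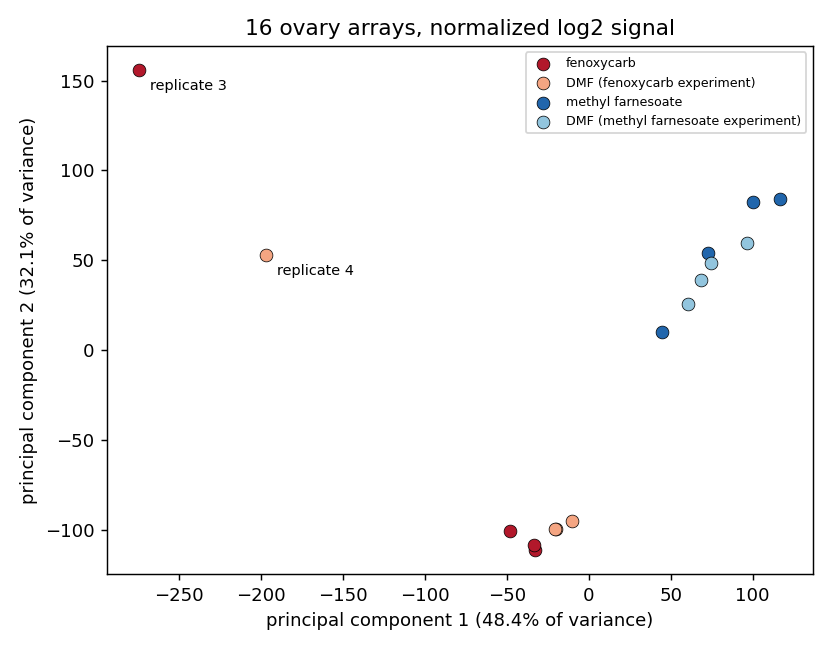
Principal components 1 (48.4% of the variance) and 2 (32.1%) of normalized log2 signal, with 1 point per array coloured by group. Fenoxycarb replicate 3 and DMF replicate 4 of the fenoxycarb experiment lie far to the left of the other 14 arrays, which split by experiment.

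Fenoxycarb raised 16 probes and lowered 0 (limma, Benjamini-Hochberg adjusted p below 0.05, 4 arrays against 4). The spread of each probe was estimated from all 16 arrays, so each SE, for either compound, also reflects the arrays of the other experiment. The median SD between replicates was 0.79 and 0.55 in the fenoxycarb experiment, and 0.22 and 0.15 in the methyl farnesoate experiment. At a typical probe the shared estimate is therefore too small for fenoxycarb and too large for methyl farnesoate. The largest increases were at DM07245_2 and DMAG0001S00001856, whose sequences overlap. DM07245_1, which shares the ID stem of DM07245_2, had a smaller mean effect of both compounds, 2.72 log2 units, and was not called in that mean. DM07245_2 was well above background on all 4 fenoxycarb arrays and on 0 of the 4 control arrays, so its increase has only a lower bound: it was at least 17.5-fold higher, with a measured log2 difference of 5.77 ± 0.70 (SE, n = 4, limma adjusted p = 0.00399). Its normalized log2 signal was -0.51 ± 0.44 (SD, n = 4) with fenoxycarb and -6.28 ± 1.06 (SD, n = 4) with DMF. DMAG0001S00001856 rose by 4.87 ± 0.46 log2 units (SE, n = 4, limma adjusted p = 0.000485), a fold of 29.2, from a control signal well above background on 3 of 4 arrays. For both probes all 4 treated arrays lay above all 4 controls. The 16 probes form 11 sequence groups, that is, sets of probes that share an ID stem or an identical stretch of 25 bases. The smallest measured increase called was 1.06 log2 units. For 5 of the 16 probes no control array was well above background, so their measured increases are uncertain and only a smaller lower bound holds. All 4 control arrays were well above background for only 4 of the 16, so most of the other increases are uncertain too. At an unadjusted p below 0.05 there were 438 probes, 289 of them higher with fenoxycarb, where chance alone, with evenly spread p-values, would give 1616. A count so far below that number means that p-values ran high over most probes, so it does not measure how much signal there is. Without the pair of arrays that stood apart 41 probes passed, 38 higher and 3 lower, and 15 of the 16 were among them. With arrays weighted by their spread 262 probes were higher and 93 lower. Without fenoxycarb replicate 1 the count was 10, and without fenoxycarb replicate 3 it was 29. The count fell to 1 when only the 8 arrays of this experiment were fitted, to 0 after normexp background correction, and to 8 higher and 1 lower under quantile normalization or median centring. It was 5 when a few high local backgrounds were replaced before normexp, a choice made after the result was seen.

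Methyl farnesoate raised 29 probes and lowered 0 (limma, adjusted p below 0.05, 4 arrays against 4). DM07245_2 had the largest measured change, rising by 4.76 ± 0.70 log2 units (SE, n = 4, limma adjusted p = 0.0159), a fold of 27.1. Its control was well above background on 3 of 4 arrays and uneven, with processed signals from 7.79 to 167, and the call was lost under 9 of 28 alternative settings, with adjusted p up to 0.579. DMAG0001S00001856 rose by 4.00 ± 0.46 log2 units (SE, n = 4, limma adjusted p = 0.00233), with all 4 controls well above background but uneven, from 31.8 to 316. Without DMF replicate 1, the brightest control for both probes, the log2 difference was 4.64 for DMAG0001S00001856 and 5.59 for DM07245_2. DM06100_1 was well above background on all 4 methyl farnesoate arrays and on 0 of the 4 controls, at least 6.51-fold higher, with a measured log2 difference of 4.26 ± 0.36 (SE, n = 4, limma adjusted p = 0.000368). For each of these probes all 4 treated arrays lay above all 4 controls. The 29 probes form 19 sequence groups, with a smallest measured increase of 1.00 log2 units, and 6 of the 29 probes had no control array well above background. All 4 control arrays were well above background for 18 of the 29. At an unadjusted p below 0.05 there were 368 probes, 248 of them higher with methyl farnesoate, again fewer than the 1616 that evenly spread p-values would give. In a fit of the 8 arrays of this experiment alone 3.88% of all probes reached that limit. Without the pair of arrays that stood apart, which belong to the other experiment and act here only through the shared estimate of spread, 87 probes were higher and 36 lower, and all 29 were among them. A fit of the 8 arrays of this experiment alone gave 109, with 78 higher and 31 lower, while 12 passed with slide as a block and 0 after normexp background correction. With a few high local backgrounds replaced before normexp, a choice made after the result was seen, 34 passed. Without DMF replicate 2 or DMF replicate 3 the count was 8, without methyl farnesoate replicate 2 it was 11, and another split of these 8 arrays into 4 and 4 called 133 probes.

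Averaged over both compounds, 49 probes were higher and 3 lower in treated ovaries (limma test of the mean of both effects, adjusted p below 0.05). All 52 had the same measured sign under each compound, but a call in the mean does not establish a change under each: 16 of the 52 were also called in the test of fenoxycarb, 27 in that of methyl farnesoate and 20 in neither. DM07221_2 and DM06269_2, for example, were not well above background on any array of the fenoxycarb experiment. The probes that rose form 29 sequence groups, 18 of which had more than 1 probe called. In the groups of DM08957_1, DMAG0001S00008977, DM07199_2, DM11877_1 and DMAG0001S00002536 those probes carry an identical sequence. Such groups show no agreement between different probes. The 16 other probes of those 29 groups that passed the filter had a median mean effect of 1.41 log2 units, and 14 of them were above 0. Among these 16, the other probe of the DM07199_2 group repeats the called sequence. The lowest of the 16, at -0.12 log2 units, belongs to the group of DM06269_2. DM06100_1 and DM06100_2, different probes with one ID stem, had the smallest adjusted p, that of DM06100_2 tied with DMAG0001S00001856. DM06100_1 (limma adjusted p = 6.3e-06 for the mean) was not well above background on any control array, so only bounds are given: at least 3.52-fold higher with fenoxycarb and at least 6.51-fold higher with methyl farnesoate. DM06100_2 had a mean effect of 2.55 ± 0.19 log2 units (SE, limma adjusted p = 1.81e-05), from 2.89 with fenoxycarb and 2.22 with methyl farnesoate, and was well above background in all treated arrays and in 3 of 4 and 4 of 4 controls. The probe sequence of DM06100_1 is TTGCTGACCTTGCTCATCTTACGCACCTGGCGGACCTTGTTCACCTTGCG and that of DM07245_2 is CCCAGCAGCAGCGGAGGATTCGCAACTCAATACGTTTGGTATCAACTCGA. The 3 probes that fell carry a single sequence, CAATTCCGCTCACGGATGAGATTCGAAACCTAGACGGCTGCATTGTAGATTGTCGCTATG. On DM04595_2 the mean effect was -1.12 ± 0.20 log2 units (SE, limma adjusted p = 0.0436) and on DMAG0001S00003832 it was -1.12 ± 0.20 (SE, limma adjusted p = 0.0436). All 4 treated arrays lay below all 4 controls in each experiment for both. The fall passed for neither compound alone, and for DM04595_2 it passed under 8 of 28 alternative settings, with adjusted p from 0.00423 to 0.606. Without the pair of arrays that stood apart 104 probes passed, 98 higher and 6 lower, and with normexp background correction 0 passed. After a few high local backgrounds were replaced before normexp, a choice made after the result was seen, 28 passed.

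**Figure D2:**
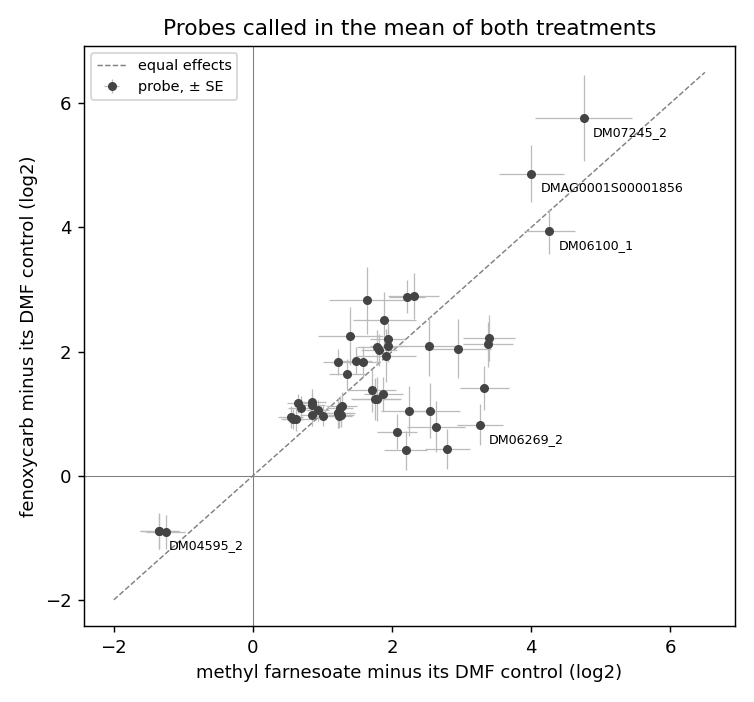
Log2 effect of fenoxycarb (vertical axis) against that of methyl farnesoate (horizontal axis), each relative to its own DMF control, for the 52 probes called in the mean of both. Points are probes, bars are standard errors and the dashed line marks equal effects. The 49 probes that rose lie above 0 on both axes and the 3 that fell lie below 0 on both.

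**Figure D3:**
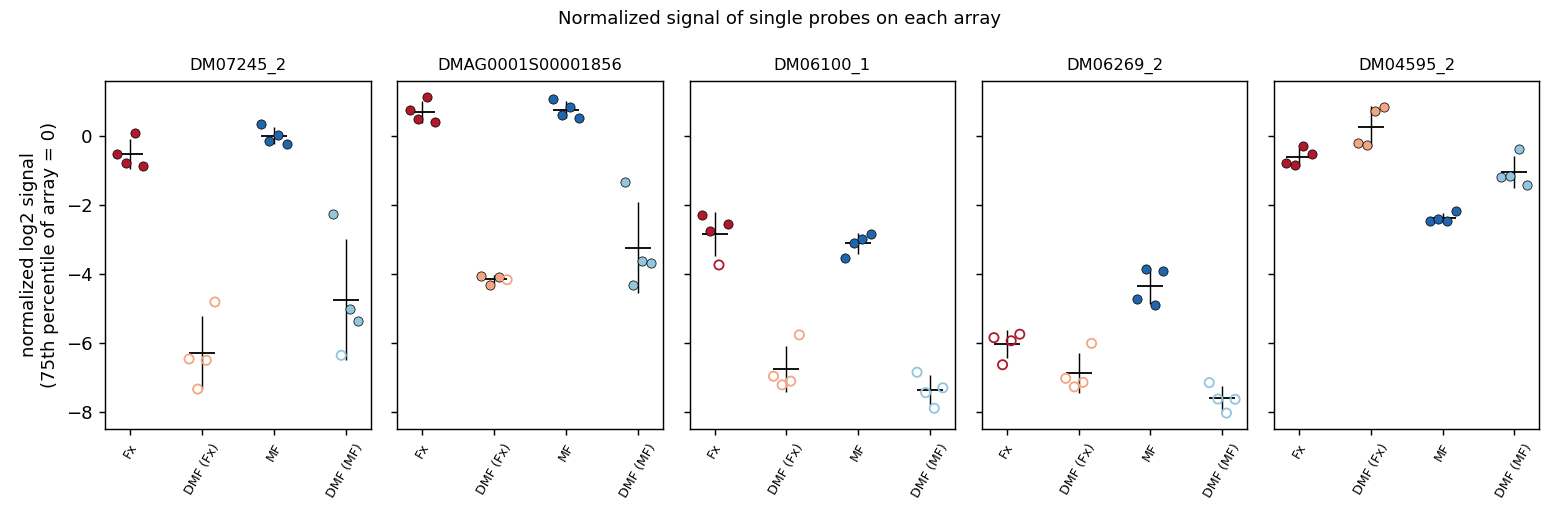
Normalized log2 signal (75th percentile of each array set to 0) of 5 probes on each of the 16 arrays, by group: fenoxycarb (Fx), methyl farnesoate (MF) and their DMF controls. Filled points were well above background, open points were not, and bars give the mean and SD (n = 4). At DM07245_2, DMAG0001S00001856 and DM06100_1 all 4 treated arrays lie above all 4 controls in both experiments.

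The experiments share no array, so calls in one could be set against the other. Of the probes called, 11 rose under both compounds, in 7 sequence groups. Both lists come from a fit with one standard error per probe, so they are not independent and no number expected by chance is given. All 34 probes called for either compound had a measured log2 above 0 under both, though 5 of them were not well above background on any array of the fenoxycarb experiment. The 16 probes raised by fenoxycarb were each tested in the 8 arrays of the methyl farnesoate experiment alone. All 16 were higher there with adjusted p below 0.05 (limma, adjusted over the list alone), by a median of 1.80 log2 units. These probes were selected in the fit of all 16 arrays, whose spread includes the arrays they were tested in. Selected in the 8 arrays of the fenoxycarb experiment alone, 1 probe passed, DMAG0001S00001856, which was 4.00 log2 units higher with methyl farnesoate. In the opposite direction, 109 probes passed for methyl farnesoate in its own 8 arrays. In the 8 arrays of the fenoxycarb experiment 89 of these had the same sign and 37 had it with an unadjusted p below 0.05 (limma), which 1.17% of all probes reached in either direction. Across all probes the effects hardly went together, with a Pearson correlation of 0.0907 and a Spearman correlation of 0.219 over probes, which are not independent replicates. They were -0.0423 and 0.0576 without the pair of arrays that stood apart. Among 99 other splits of the arrays within both experiments 40 gave a Pearson correlation at least as far from 0.

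The slide is a technical batch, with 2 treated arrays and 2 of their own controls on each of 4 slides. The 49 probes higher in the mean were all higher in treated arrays within each slide, by a median of 1.19 and 1.41 log2 units on the slides of the fenoxycarb experiment and 1.77 and 1.60 on those of the methyl farnesoate experiment. They were selected on these same arrays. Across all probes the effects on the slides of the fenoxycarb experiment correlated at -0.72 and those on the slides of the methyl farnesoate experiment at -0.18. Fenoxycarb replicate 3 was a treated array on slide 1, and DMF replicate 4 a control array on slide 2. Of probes over 2 log2 units off in the former, 99.4% deviated the same way in the latter. That shared deviation enters the differences with opposite signs, so the -0.72 does not show a fenoxycarb effect that reversed between slides. DMAG0001S00001856 differed by 4.97 and 4.77 log2 units on the fenoxycarb slides and by 3.52 and 4.49 on the methyl farnesoate slides. For DM04595_2 these differences were -0.17, -1.61, -1.14 and -1.55. With slide as a block the counts were 14 for fenoxycarb, 12 for methyl farnesoate and 42 for the mean of both, none of them lower.

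No probe responded differently to fenoxycarb and methyl farnesoate at the threshold: 0 of 32314 passed the test of the difference (limma, smallest adjusted p = 0.735), and 244 had an unadjusted p below 0.05. That too is fewer than the 1616 that evenly spread p-values would give. The labels used here give no dose or time for either compound, so the comparison is of the exposures as applied. The probes with the smallest unadjusted p, none of which passed, were DMAG0001S00005168 and DM02762_2 on the side of fenoxycarb and DM06269_2 and DM07221_2 on the side of methyl farnesoate. DMAG0001S00005168 had log2 values of 1.50 with fenoxycarb and -0.86 with methyl farnesoate, a difference of 2.35 (95% interval 1.48 to 3.23, limma adjusted p = 0.735), and DM02762_2 had 1.43 and -0.84, a difference of 2.26 (95% interval 1.33 to 3.19). DM06269_2 rose with methyl farnesoate, at least 2.76-fold (measured log2 difference 3.27 ± 0.33, SE, n = 4, limma adjusted p = 0.00153). Of the 3 probes of its sequence group that passed the filter, only DM06269_2 was called in the mean of both treatments. The lowest mean effect among the 3 was -0.12 log2 units, so the other probes do not bear out its rise. With fenoxycarb DM06269_2 was not well above background on any array of either group, so no fold is given there. DM07221_2 was measured likewise, at least 1.54-fold higher with methyl farnesoate and not well above background on any array of the fenoxycarb experiment. Over the 49 probes higher in the mean the median difference between the effects was 0.02 log2 units, 25 had the larger fenoxycarb effect, and the median 95% interval reached 0.85 log2 units to either side. Of the 49, 10 had an unadjusted p below 0.05 for the difference (limma), so the small median does not mean equal effects at each probe. The 49 were selected with the same standard errors, so that share cannot be set plainly against the share over all probes. Without the pair of arrays that stood apart the median difference over the 49 probes was 0.24, toward fenoxycarb, and 7 probes passed the test of the difference. With arrays weighted by their spread 107 passed.

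The control groups received the same solvent and differed far more than either treatment from its control. Of 32314 probes 6431 (19.9%) passed, 3086 higher in the DMF group of the fenoxycarb experiment and 3345 higher in that of the methyl farnesoate experiment (limma, adjusted p below 0.05). DM09934_1 and DM09934_2, overlapping probes with one ID stem, were higher in the fenoxycarb experiment, by 7.53 ± 0.23 log2 units (SE, n = 4, limma adjusted p = 3.63e-11) and 7.13 ± 0.23 (SE, n = 4, limma adjusted p = 6.35e-11). DM00608_2 and CU14701 were higher in the methyl farnesoate experiment, where their processed signals in controls ran from 99132 to 128580 and from 61228 to 73374, while they were not well above background on any array of the fenoxycarb experiment. The differences were at least 4255-fold for DM00608_2 (measured log2 difference -14.00 ± 0.34, SE, n = 4, limma adjusted p = 3.46e-12) and at least 2474-fold for CU14701 (measured log2 difference -13.39 ± 0.32, SE, n = 4, limma adjusted p = 3.46e-12). The treatments did not pass the test at any of these 4 probes. The control groups lay on different slides and were scanned in separate sessions, so experiment and session cannot be told apart, and the count was 17621 without the pair of arrays that stood apart and 2007 after normexp background correction. The balance of directions also turned with the processing: 10248 were higher and 2680 lower in the fenoxycarb experiment after normexp with high local backgrounds replaced, 3150 and 1734 among probes well above background on all 16 arrays, and 1349 and 2536 with a 2-fold minimum.

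Probes of identical sequence differed little within an array, with a median SD of 0.06 log2 units over 2440 sets well above background on all arrays. The median SD between replicate arrays, over all probes and groups, was 0.56.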

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

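The splits of the arrays, quantile normalization and slide as a block were planned, but the use of the latter settings to weigh causes, and all other tests below, were chosen only after the result was seen. Of 68 groups of 4 values examined for a single distant value, 8 had one, where chance gives about 3.4, and 4 of the 8 belong to the pair of arrays that stood apart.

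Fenoxycarb replicate 3 and DMF replicate 4 of the fenoxycarb experiment lay far from the rest of their groups in brightness and in profile. Their 75th percentiles of processed signal were 195.3 and 196.1, against 326 or more for the other arrays of the experiment, and their median correlations with their own groups were 0.801 and 0.910. Lower brightness alone would keep the order of probes, but the Spearman correlation of fenoxycarb replicate 3 with the mean of the 6 other arrays was 0.735, against 0.989 or more for each of those 6. Errors of single spots would leave different probes of one transcript unrelated, but over 4258 stems the deviations of non-overlapping probes of one stem correlated at 0.758 in fenoxycarb replicate 3 once the level of the probe was removed, against 0.01 for probes of different stems. RNA of a second composition in both samples may account for the pattern: of 12266 probes over 2 log2 units from the other arrays in fenoxycarb replicate 3 and with no missing value in the experiment, 97.7% deviated the same way and by less in DMF replicate 4 (40.4 to 78.4% in the other 6 arrays), to a median of 0.66 of the distance. These probes were chosen for a large deviation in fenoxycarb replicate 3, so a smaller one elsewhere was nearly fixed in advance. Direction alone was shared by 99.4% in DMF replicate 4 and by 40.5 to 78.5% in the other 6 arrays. Scaling to their low 75th percentiles raised the probes of both distant arrays, which favours a shared upward direction. A smaller share of such RNA in DMF replicate 4 is not shown by these counts. A fit over 23780 probes, not chosen by their deviation, gave weights of 0.37 for the mean of the 6 other arrays and 0.57 for fenoxycarb replicate 3. The residual SD in DMF replicate 4 was 0.40 log2 units, against 1.22 and 0.82 for either alone. The profile of DMF replicate 4 thus lay between them, which does not show that RNA was mixed. What RNA of a second composition would be, such as other tissue, another ovarian stage or degraded RNA, was not tested, and no biological explanation was tested because the arrays belong to opposite groups.

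The rise of 49 probes in the mean of both treatments was weighed against those arrays and against the slides. Without the pair of arrays 46 of the 49 were still called higher, which argues against that pair as the whole cause. Every slide held 2 treated and 2 control arrays, so an effect common to a slide cancels in the comparison by design, and the 41 still called with slide as a block add nothing to that. An effect of the treatments, which the design names, stays open as a hypothesis. By a limit of 5% of splits, chance can be excluded for the mean of both treatments, where 1 of 100 splits of the arrays, the real one, called 52 or more probes and the highest other split called 3. Among the 33 of these splits that keep 2 arrays of each side on every slide, a comparison added after the result was seen, 1 called as many. For fenoxycarb 1 of 35 splits, the real one, called 16 or more and the highest other called 3, so chance can be excluded if arrays may be exchanged across slides. Within slides there are only 18 splits, too few for a share under 5%, and the highest other called 0. For methyl farnesoate it cannot, since 2 of 35 splits called 29 or more. One other split called 133 probes, setting methyl farnesoate replicates 1 and 3 with DMF replicates 1 and 4 against the rest, which points to a structure among these samples that follows neither the treatment nor the slide. For the difference between the treatments the splits decide nothing: with 0 calls, 100 of 100 splits reach that count by construction.

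The difference between the DMF control groups was weighed against scaling and processing. Quantile normalization, which gives every array one distribution, gave 5872 calls against 6431, which argues against a difference in brightness between scan sessions as the whole cause. Slides and sessions of the experiments were separate, and although 8695 probes passed with slide as a random block, no slide held both control groups, so processing of the experiments apart from each other and a biological difference between the cultures cannot be told apart. Chance can be excluded by the same limit for single arrays, since 1 of 35 splits of the 8 control arrays called as many as 6431 and the highest other called 0, but with whole slides as units there are too few splits to decide.

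DMF replicate 1 of the methyl farnesoate experiment was brighter than its group, with a 75th percentile of 790.6 against 658 for the next array, and its median correlation with its group was 0.967 against 0.991 for the next. Methyl farnesoate replicate 1, which was not flagged by this rule, was also the brightest of its group, at 809 against 650 for the next. Its deviations from its group mean correlated at 0.679 with those of DMF replicate 1, and at -0.233 or less with those of the other controls. DM06100_2 had a normalized log2 signal of -2.31 in methyl farnesoate replicate 1 against -1.85 in the nearest replicate. DM09934_2 had -3.12 in DMF replicate 4 of the methyl farnesoate experiment against -2.63 in the nearest replicate.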

How the results depend on the processing

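Leaving out the pair of arrays that stood apart, array weights, replaced local backgrounds and sequence groups were chosen after the result was seen. In order, counts below are for fenoxycarb, methyl farnesoate, the mean of both, their difference and the DMF controls, against 16, 29, 52, 0 and 6431. Normexp gave 0, 0, 0, 0 and 2007 and moved the median fenoxycarb effect over all probes by -0.35. A few spots with local backgrounds above their signal, down to a signal minus background of -60391, raised the 5th percentile of the corrected signal to 485 and 756 in DMF replicates 3 and 4 of the fenoxycarb experiment, against 60.7 or less in the other 6. In the methyl farnesoate experiment it rose to 304 in DMF replicate 3 and 112 in methyl farnesoate replicate 3, against 64.2 or less. With these backgrounds replaced the counts were 5, 34, 28, 0 and 12928. For the other changes the cause was not tested. Quantile normalization gave 9, 17, 40, 2 and 5872, and median centring 9, 11, 26, 0 and 4684. Requiring probes well above background on all 16 arrays, which tests 23746 probes, gave 2, 8, 15, 0 and 4884. Own 8 arrays gave 1, 109 and, for controls, 8089. Slide as a block gave 14, 12, 42, 0 and, as a random block with an estimated correlation of -0.25, 8695. A 2-fold minimum left 3885 between controls. Without the pair of arrays the counts were 41, 1.2e+02 (87 higher and 36 lower), 104, 7 and 17621, with array weights 355, 260, 330, 107 and 21839, and with 1 probe per sequence group 8, 15, 23, 0 and 3435. Leaving out each array gave 10 to 29, 8 to 53, 38 to 71, 0 to 0 and 4649 to 11829. Fenoxycarb passed at 10 probes without fenoxycarb replicate 1 and 29 without replicate 3. Methyl farnesoate passed at 53 without fenoxycarb replicate 3, at 11 and 14 without its replicates 2 and 3, and at 8, 8 and 17 without its DMF replicates 2, 3 and 4. Controls differed at 11829 without fenoxycarb replicate 3. The correlation of the effects, 0.0907, was -0.0423 without the pair, -0.164 with array weights and -0.0789 to 0.208 with each array left out.

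Replicate numbers did not pair the samples: the correlations of deviations at equal numbers ran from -0.848 to 0.679, and not every sample correlated best with its own number. With the replicate block the counts were 12, 16, 43, 0 and 5515. No named effect changed sign under any alternative. Gene counts, gene set tests and the choice of probe for a gene were not run, since no probe has a gene name. Signal over background limits probes such as DM06100_1, whose controls give only a bound.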

Other observations

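A small set of probes, singled out after their values were seen, marked the experiments in an all-or-none way. In the methyl farnesoate experiment 577 probes were well above background on all 8 arrays and on 0 of the 8 arrays of the fenoxycarb experiment, and 1 probe had the opposite pattern. The arrays of the methyl farnesoate experiment were also brighter throughout, with 75th percentiles of 590 to 809 against 195.3 to 359, which favours this direction. With no regard to the background flag, after scaling, 39 probes were over 64-fold brighter on every array of that experiment and 2 on every array of the other. For 7 of the 577, in 4 sequence groups, every array of the methyl farnesoate experiment was over 64-fold brighter than every array of the other. DM00608_2 was the brightest of them, with processed signals of 98756 to 133150 in the methyl farnesoate group and 2.12 to 3.60 in the fenoxycarb group. CU14701 had 56788 to 68728 and 2.11 to 3.15 in the same groups, CU14422 had 21766 to 33764 and 2.35 to 6.13, and CU91 had 14439 to 18777 and 2.21 to 3.90. Treated and control arrays of an experiment did not differ at the threshold in any of the 7. No explanation was tested. The RNA that these probes bind was not identified, so an all-or-none difference in gene expression is not shown.

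Both DM06100 probes, named for their shared rise, hold repeats, which was seen after their values. The most frequent word of 6 bases occurs 3 times in DM06100_1 and 4 times in DM06100_2, and 1.48% and 0.493% of all probes have a word that occurs as often. Binding of other transcripts with such repeats was not tested.

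Leaving out the pair of arrays that stood apart, a choice made after the data were seen, gave 7 probes whose response differed between the treatments. The largest difference was at DM10904_1, with log2 values of -2.74 for fenoxycarb and -0.14 for methyl farnesoate, a difference of -2.60 ± 0.25 (SE, limma adjusted p = 0.00709, 3 arrays per group in the fenoxycarb experiment). The other 6 went the opposite way, and 3 of them, DM05703_1, DM05703_2 and DMAG0001S00006990, form 1 sequence group with differences of 1.79, 1.72 and 1.78. Each was above 0 for fenoxycarb and below 0 for methyl farnesoate. With all arrays 0 probes passed this test.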
